A study of Mus musculus with 4 samples.

How the data were processed

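RNA sequencing measured gene expression in 4 libraries of mouse T cells, 1 library for each combination of 2 T cell receptors (TRP1high and TRP1low) and 2 peptides (K8 and M9), after 48 h of co-culture with peptide-loaded B cells and cell sorting. The groups were taken from the sample titles in the labels. Per the file headers, the authors deposited log2 normalized counts, 1 value per gene symbol and library, and all values here are on that log2 scale. The smallest value was exactly 0 in each library. After the logarithm was undone and 1 was taken away, the low values piled up at whole multiples of 1 step per library, so the unit was read as the log2 of an estimated count divided by 1 size factor per library, plus 1. Salmon 0.8.2, DESeq2 1.20.0 and the mouse build mm10 are named in the submitters' processing notes, and their settings are not given in the sources used here. The transcript annotation and any filter used by the authors are not given in the sources used here.

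Each library's step gave the worth of 1 read, which was 0.998, 0.989, 1.37 and 1.05 normalized counts in TRP1high with K8, TRP1high with M9, TRP1low with K8 and TRP1low with M9. In that order, dividing by the step gave 40.5, 41.5, 29.6 and 40.3 M estimated reads, and 633, 672, 1205 and 769 genes were at 0. A gene at 0 was compared through a floor of 3 reads, which lies at log2 2.00, 1.99, 2.35 and 2.05. Folds of genes at or under the floor in both libraries are not given. Counts of list members 2-fold apart rest on the log2(value + 1) scale and take in some members within the floor in both libraries of a pair: Gzmk, Il13, Ccl1, Il24, Csf1r, Siglech and Alas2. Counting intervals of ratios are 95% exact (Clopper-Pearson) intervals on the estimated reads, and shares of reads have 95% Wilson intervals. Both cover counting error only, since the reads carry no molecular identifiers. Between 56.2% and 56.4% of the values from 0 to 50 lay within 0.01 of a whole read. Whole reads could thus not be recovered for the other values, and no negative binomial test (edgeR or DESeq2) was run.

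The files hold 16338 rows, of which 16171 (98.98%) had a symbol in GENCODE M21, the GRCm38 (mm10) annotation used for positions and gene types. Date-like names stood in 20 rows and 1 name was repeated, and 47 rows were at 0 in all libraries. The 16102 genes with a mean of at least 1 normalized count over the 4 libraries were tested. The deposited scaling was kept: the median log2 ratio of each library to the mean of the 4 was -0.004, -0.019, 0.018 and 0.026.

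Each of the 4 single comparisons (M9 against K8 in each TCR, and TRP1high against TRP1low with each peptide) is a log2 difference between 2 libraries with no p-value, and genes at least 2-fold apart with at least 10 normalized counts in 1 of the pair were counted. That fold is on the log2(value + 1) scale, while folds printed for single genes are ratios of normalized counts without the added 1. For counting intervals, and to tell which genes are at 0 or within the floor, estimated reads were rounded to whole reads. The difference between the peptide differences of the TCRs was counted in the same way. The agreement of each difference between its 2 separate pairs of libraries is given as a correlation across genes and as a count of genes 2-fold apart in the same direction in both, beside the number that independent lists would share. For the peptide over both TCRs and the TCR over both peptides, limma 3.58.1 in R 4.3.3 fitted an additive model of TCR and peptide (eBayes with trend and robust off), with 1 residual degree of freedom, and Benjamini-Hochberg adjustment at 0.05. The residual of that model is the disagreement of the difference between its 2 pairs. No library has a replicate in its group, so any p-value measures this disagreement and not the spread between cultures.

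The 17 gene lists, the 8 lists of cell type and sex-linked markers, the rule for named genes, the tests and the first set of alternatives were fixed before the data were examined. The gene lists were effector cytokines and chemokines, cytotoxic granule and death ligand genes, activation and costimulatory receptors, inhibitory receptors and exhaustion-associated genes, T cell receptor-induced immediate response genes, effector and lineage transcription factors, naive and memory-associated genes, cell cycle genes, glycolysis genes, oxidative phosphorylation genes, cholesterol and lipid synthesis genes, amino acid and integrated stress response genes, ribosome biogenesis genes, interferon-stimulated genes, interleukin 2 and STAT5 target genes, chemokine receptors and adhesion molecules, and p53 and apoptosis genes. The marker lists covered CD8 T cells, B cells, plasma cells, CD4 T cells, gamma delta T or NK cells, myeloid or dendritic cells, erythroid cells and sex-linked genes. A list's standing is the percentile of its median log2 difference among 10000 random lists of the same size matched on mean expression in 20 bins. It was computed for 21 lists: the 17 gene lists and the B cell, CD8 T cell, erythroid and myeloid or dendritic markers. These 21 lists were also tested with camera (limma), with a preset correlation of 0.01 between genes and with an estimated correlation. The estimated correlation rests on 1 residual degree of freedom and is poorly determined. P-values of list members were further adjusted over the list alone.

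The rule named the 10 genes with the highest and the 10 with the lowest mean difference among those 2-fold apart in the same direction in both pairs, for the peptide and for the TCR, with receptor and immunoglobulin segments left out for the TCR. It also named the 5 highest and 5 lowest genes of each single comparison, the 5 most positive and 5 most negative differences of differences, up to 4 members of each list with the largest mean difference, any list member at least 2-fold apart, and all markers. Some single genes that the rule names are not reported here, while list medians and counts include them. Pseudogenes named by this rule share reads with near-identical genes, and their values are uncertain.

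The tests were checked on simulated data. Values of 16102 genes were drawn with the fitted spread and counting noise, and 200 genes were given a peptide difference. The additive limma model called 0 of 50 genes at each of log2 differences 1, 2, 3 and 4 after adjustment, and 20, 42, 47 and 48 of 50 had an unadjusted p under 0.05. The estimated direction was right for 48, 49, 50 and 48 of 50. In this simulation the adjusted test had no power even for 16-fold differences. Its noise beyond counting error did not depend on expression level, and the trend option called 0 genes there. The simulation is thus a rough guide to the data only. The list percentile was checked on values drawn independently for each gene. There, 4 of 100 lists without a difference fell outside the 2.5 to 97.5 percentile range, and a list shifted by 1 reached percentile 100. Members of a real list can vary together, which this check left out, so a percentile is a rank and not a test. In the data, medians of 16 of 21 lists for the peptide and 14 of 21 for the TCR lay outside that range.

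Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5, rescaling by the median ratio, removal of 184 receptor, immunoglobulin, mitochondrial and B cell genes with rescaling, a 1.5-fold threshold, a minimum of 50 in 1 library, and limma with trend, with robust or without the covariate. A minimum of 200 in 1 library and the removal of pseudogenes and receptor segments were chosen after seeing the data. The plan assumed TPM or another normalized unit. The files hold log2 normalized counts, and the planned steps for normalized values were used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the other computations.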

Results

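Gene expression was measured by RNA sequencing in mouse T cells that carried 1 of 2 T cell receptors (TCRs), named TRP1high and TRP1low, after stimulation for 48 h by B cells loaded with 1 of 2 peptides, named K8 and M9. TRP1 is tyrosinase-related protein 1, a pigment cell protein that serves as a melanoma antigen. T cells were sorted from the co-culture before total RNA was prepared, and the series concerns CD8 T cell effector function under altered peptide binding to MHC class I. Each of the 4 groups held 1 library, so no value has a replicate and no difference could be set against the spread between cultures. The libraries held 40.5 M estimated reads in TRP1high with K8, 41.5 M in TRP1high with M9, 29.6 M in TRP1low with K8 and 40.3 M in TRP1low with M9. Across 16102 genes, Pearson correlations between libraries ran from 0.93 (TRP1high with M9 and TRP1low with K8) to 0.97 (both TRP1high libraries). Values are log2 normalized counts plus 1, as deposited.

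The receptor transcripts separated the libraries by TCR as labelled. In TRP1high, Trbv13-3 (chromosome 6, 41130147 to 41130585, mm10) held 84.8% of Trbv reads with K8 (95% Wilson interval 83.9 to 85.6) and 89.9% with M9 (89.3 to 90.5), and Traj42 held 90.7% (88.6 to 92.5) and 88.3% (86.2 to 90.1) of Traj reads. In TRP1low, Trbv12-1 (chromosome 6, 41113550 to 41114067) held 99.6% (99.4 to 99.7) and 99.9% (99.8 to 99.9), and Traj26 held 73.5% (67.5 to 78.7) and 72.3% (67.7 to 76.5). Trbv12-1 had 1 and 3 reads in the TRP1high libraries, and Trbv13-3 had 4 and 2 in the TRP1low libraries. Of the Trav reads of TRP1high, the near-identical copies Trav6-6, Trav6d-6 and Trav6n-6 held 27.1%, 27.1% and 22.6% with K8 and 28.5%, 28.5% and 25.5% with M9, and 72.0% (69.7 to 74.2) and 75.7% (73.9 to 77.4) of those of TRP1low fell on Trav6-5. The constant gene Trbc1 had 2013 and 3431 estimated reads in TRP1high with K8 and M9 and 23155 and 31345 in TRP1low.

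The first comparison asks how the T cell transcriptome differed between stimulation by the M9 and by the K8 peptide. In both TCRs, the M9 library held more Prf1 and more transcript of several inhibitory receptors and TCR-induced genes, and less Gzma and transcript of several chemokine receptors. Prf1, the pore-forming protein of cytotoxic granules (chromosome 10, 61297833 to 61304680), was 11.0-fold higher in the M9 library of TRP1high and 6.90-fold higher in that of TRP1low. Cd200, a cell surface glycoprotein (chromosome 16, 45382135 to 45409053), was 6.76-fold and 11.5-fold higher, and Tnfrsf4, the costimulatory receptor OX40 (chromosome 4, 156013843 to 156016612), was 4.72-fold and 7.19-fold higher. Cxcr3, a chemokine receptor of effector T cells (chromosome X, 101731535 to 101734269), was 11.9-fold and 10.7-fold lower, and Gzma, a granzyme (chromosome 13, 113093825 to 113100981), was lower by log2 differences of -3.59 and -6.71.

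At least 2-fold differences between M9 and K8 were seen for 1589 genes in TRP1high (828 higher and 761 lower with M9, 9.87% of 16102) and for 2431 in TRP1low (1235 higher and 1196 lower, 15.1%). Both TCRs shared 255 of the higher and 252 of the lower genes, against 58.2 and 41.8 for independent lists, while 184 genes differed in opposite directions, against 98.7. Across 12580 genes, which are not independent replicates, the differences of the 2 TCRs had a Pearson correlation of 0.30 and a Spearman correlation of 0.30. Among genes with at least 200 normalized counts in 1 library of each pair, a limit chosen after seeing the data, 147 genes were shared, against 12.6, with a Pearson correlation of 0.42.

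**Figure D1:**
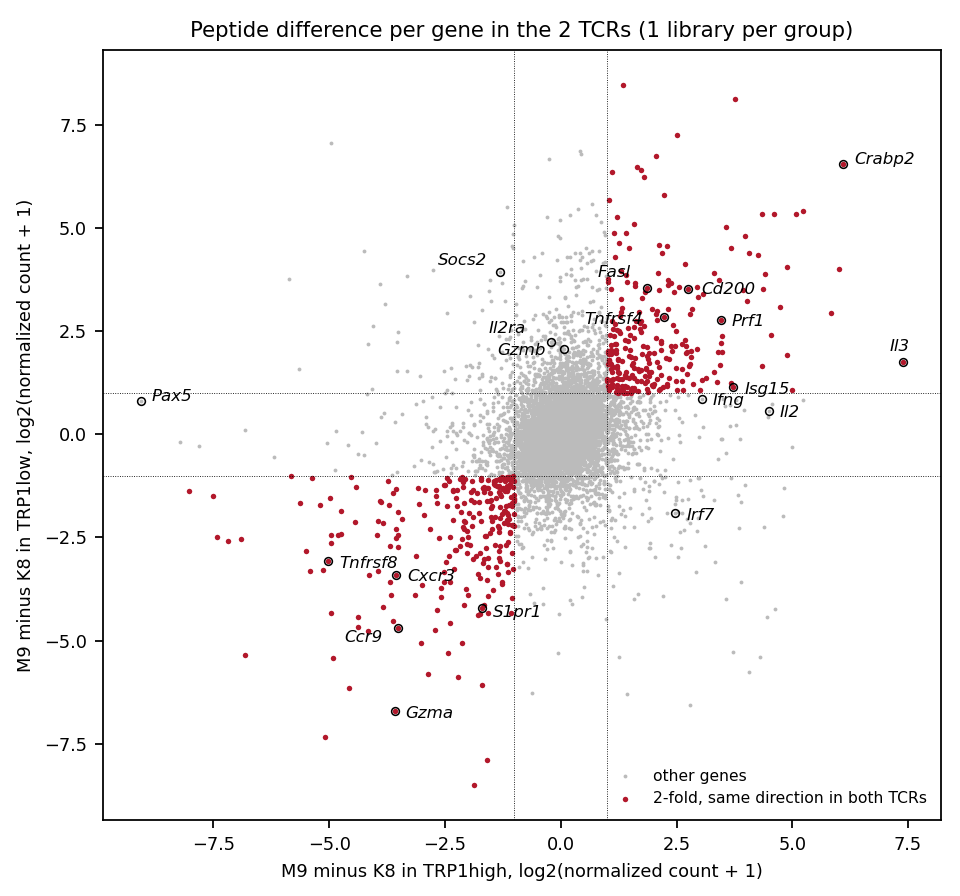
Each point is 1 gene with at least 10 normalized counts in 1 library of both pairs, with its M9 minus K8 difference in TRP1high (horizontal axis) and TRP1low (vertical axis), both as log2(normalized count + 1), 1 library per group. Red points are the 507 genes 2-fold apart in the same direction in both TCRs, dotted lines mark 2-fold, and Prf1, Cd200 and Tnfrsf4 lie at the upper right while Cxcr3, Ccr9 and Gzma lie at the lower left.

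Crabp2, a retinoic acid binding protein (chromosome 3, 87948666 to 87953376), had the highest mean difference, at 71.5-fold and 100.7-fold higher with M9. Il3, a cytokine gene (chromosome 11, 54265303 to 54267277), was at least 55.5-fold higher in TRP1high, where the K8 library held 0 reads, and 3.51-fold higher in TRP1low. Myh10, a nonmuscle myosin heavy chain, was 13.7-fold higher in TRP1high and at least 68.7-fold higher in TRP1low, and Nectin1 was 5.95-fold and at least 36.9-fold higher. Igfbp7 was 20.8-fold higher in TRP1high and 69.1-fold higher in TRP1low, where 1 K8 read left a counting interval of 12.1 to 2756. Wisp1 was at least 12.2-fold and 10.2-fold higher. Cnih3 was 101.7-fold higher in TRP1high (24.1 to 734) and at least 3.68-fold higher in TRP1low, and Adamts17 was 39.2-fold (8.16 to 259) and 95.9-fold (8.64 to 1999) higher. Among the lowest, Mzb1, a gene of B and plasma cells, was 59.5-fold (10.3 to 2390) and 82.2-fold (14.2 to 3296) lower, Pet117 was at least 7.73-fold and 22.2-fold lower, and Pde2a was 3.23-fold and at least 74.8-fold lower. The histone genes Hist1h2ao (2.57-fold and at least 86.1-fold higher) and Hist1h2ap (lower in both) belong to a family of near-identical copies, and the pseudogenes Gm7984 (higher) and Gm11914, Gm2274 and Gm2981 (lower) share sequence with other genes, so that their values are uncertain. The unnamed gene models Gm9774 and Gm20431 (both lower) completed the 20. In single comparisons, Impg2 was at least 39.0-fold higher and Exosc6 at least 75.3-fold lower with M9 in TRP1high, and Plb1 was at least 85.7-fold lower in TRP1low.

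Of the 19 measured cytotoxic granule and death ligand genes, 4 were at least 2-fold higher with M9 in both TCRs and 4 at least 2-fold lower. The higher ones were Prf1, Fasl (the Fas ligand, log2 difference 1.86 and 3.54), Klrk1 (the activating receptor NKG2D, 2.16 and 2.25) and Srgn (serglycin, the granule proteoglycan, 1.52 and 1.09). The lower ones were Gzma, Gzmk, Gzmf (-2.33 and -1.36) and Tnfsf10 (the death ligand TRAIL, -1.51 and -1.58). Gzmk was at least 19.4-fold lower with M9 in TRP1low, and within the floor in both TRP1high libraries. Gzmb, the most abundant granzyme, stood at log2 17.12 and 17.19 with K8 and M9 in TRP1high, and at 14.89 and 16.97 in TRP1low. The list's median difference was 0.13 (91.1st percentile of random lists) and 0.09 (68.0th), and Prf1 (3.12, SE 0.29) and Klrk1 (2.21, SE 0.19) had an adjusted p of 0.040 in limma with Benjamini-Hochberg values adjusted over the list alone, against 0.58 over all genes.

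Of 23 measured effector cytokine and chemokine genes, 11 were at least 2-fold higher and 4 lower with M9 in TRP1high, and 7 were higher and 4 lower in TRP1low. The chemokines Ccl3 (3.44 and 1.68) and Ccl4 (2.82 and 2.03) and the cytokine Il3 were the 3 members at least 2-fold higher in both, and 1 member was at least 2-fold lower in both. In TRP1high, Il2 (interleukin 2) was 4.49, Ifng (interferon gamma) 3.04 and the chemokine Xcl1 3.40 higher on the log2 scale, against 0.58, 0.87 and -0.60 in TRP1low. Tnf was near level in both (-0.52 and -0.19). The list's median was 0.87 in TRP1high (100th percentile) and 0.03 in TRP1low (48.2nd). With values under the floor raised to it, the median was -0.13 in TRP1low.

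Among 16 measured inhibitory receptors and exhaustion-associated genes, 7 were at least 2-fold higher with M9 in both TCRs and 2 lower. Pdcd1, which encodes PD-1, was 2.17 and 1.43 higher on the log2 scale, Lag3 1.81 and 2.62, Tigit 1.96 and 3.05, Btla 1.04 and 1.14, Nrn1 2.33 and 1.38 and Klrc1 3.38 and 1.26. Havcr2, which encodes TIM-3, was lower (-1.91 and -2.22), as was Cd200r1, a receptor for CD200 (-3.51 and -2.73), both at few reads. Ctla4 differed in direction between TCRs (-0.46 and 1.57). With p-values adjusted over the list alone, 8 of 16 members (Pdcd1, Lag3, Tigit, Btla, Cd200, Nrn1, Havcr2 and Cd200r1) had a limma Benjamini-Hochberg adjusted p from 0.030 to 0.048, against 0.58 over all genes. The median was 0.55 in TRP1high (99.98th percentile) and 1.203 in TRP1low (100th), and camera gave an adjusted p of 0.22. Against the mean of the other 3 libraries, the list's median was -1.05 in TRP1low with K8 and 0.90 in TRP1high with M9.

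The 31 T cell receptor-induced immediate response genes had a median of 0.96 in TRP1high and 0.68 in TRP1low, both at the 100th percentile. With M9, 15 were at least 2-fold higher and 0 lower in TRP1high, and 10 were higher and 1 lower in TRP1low. The 7 that were higher in both were Nr4a2 (1.84 and 1.61) and Nr4a3 (1.69 and 2.98), orphan nuclear receptors induced by TCR signals, Spry1 (2.38 and 3.67), Spry2 (2.30 and 1.23), Fosl2 (2.34 and 1.83), Cd5 (1.58 and 1.62) and Dusp5 (1.19 and 1.03). Tnfaip3, an inhibitor of NF-kB signalling, was the 1 lower gene in TRP1low (-1.45) and was 0.83 higher in TRP1high. Camera gave an adjusted p of 7.7e-06 for this list with the preset correlation, and the call was lost at an adjusted p = 0.84 with an estimated correlation. Adjusted over the list alone, 0 of the 31 members passed in limma, and 11 had an unadjusted p under 0.05. Against the mean of the other 3 libraries, this list stood at -0.66 in TRP1low with K8 and at 0.71 in TRP1high with M9.

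The 16 measured chemokine receptors and adhesion molecules had a median of -1.06 in TRP1high and -1.96 in TRP1low, both at percentile 0. Cxcr3, Cxcr5 (-1.998 and -2.49), Cxcr6 (-1.16 and -1.91), Ccr2 (-1.90 and -1.998), Ccr9 (a gut-homing receptor, -3.53 and -4.70) and Itgae (the integrin CD103, -1.75 and -4.36) were at least 2-fold lower with M9 in both TCRs, and Cx3cr1 was higher (2.23 and 2.81) at few reads. S1pr1, which guides T cell egress from lymphoid tissue, was 3.27-fold and 18.7-fold lower, and Klf2, a transcription factor that induces S1pr1, was lower (-1.22 and -2.14). Adjusted over the list alone, 5 of 16 members (Cxcr3, Cxcr5, Ccr2, Ccr9 and Cx3cr1) had a limma Benjamini-Hochberg adjusted p of 0.021, against 0.58 over all genes. Compared with the other 3 libraries, the list's median was 1.93 in TRP1low with K8 and -1.30 in TRP1high with M9. Markers of B cells, which also express members such as Cxcr5, were lower with M9 too (medians of -3.62 and -1.21). Against the other 3 libraries they stood at 0.88 in TRP1low with K8, but were highest in TRP1high with K8 (2.22), where this list stood at 0.18. Myeloid markers, whose cells express Ccr2, stood at 1.79 in TRP1low with K8. How much of this list's transcript came from such cells was not tested. The list's camera adjusted p was 2.5e-04, and the call was lost at an adjusted p = 0.84 with an estimated correlation.

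Transcription factors and activation receptors went both ways. Ikzf2 (Helios, -2.10 and -2.30) and Id2 (-1.66 and -1.41) were the 2 of 16 effector and lineage transcription factors at least 2-fold lower with M9 in both TCRs, and Tbx21 (T-bet, 0.27 and 0.28) was near level. Zeb2, a factor of terminal effector cells, was 2.74 and 0.96 higher. The list's median was -0.44 (percentile 0.07) in TRP1high and 0.05 (55.9) in TRP1low. In TRP1low the median with values under the floor raised to it was -0.20. Of 21 activation and costimulatory receptors, Tnfrsf4 and Slamf1 (1.08 and 2.04) were higher in both and Tnfrsf8, which encodes CD30, was 33.6-fold and 8.57-fold lower. That list's median was -0.05 in TRP1high and 0.32 in TRP1low (99.9th percentile). Of 22 naive and memory-associated genes, 2 (S1pr1 and Klf2) were lower and 0 higher in both, with medians of 0.01 and -0.30.

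Glycolysis, cholesterol synthesis, interleukin 2 target and amino acid stress lists had higher medians in the TRP1low pair than in the TRP1high pair, a difference that was not tested. Of 22 glycolysis genes, 9 were at least 2-fold higher with M9 in TRP1low, where Slc16a3, a lactate transporter, was 18.1-fold and Bnip3 2.87 log2 higher, and 0 passed 2-fold in TRP1high, where Slc16a3 was 1.93-fold higher. Medians were 0.70 in TRP1low and 0.34 in TRP1high, both at the 100th percentile. The 22 cholesterol and lipid synthesis genes had a median of 0.65 (100th percentile) in TRP1low and -0.01 (68.7) in TRP1high, and the desaturase Scd1 was 10.5-fold and 1.25-fold higher. The 14 interleukin 2 and STAT5 target genes had a median of 0.84 (100th percentile) in TRP1low, with 7 at least 2-fold higher, and of -0.21 (2.35) in TRP1high. Among them were Il2ra (the interleukin 2 receptor alpha chain, 2.25 in TRP1low and -0.21 in TRP1high), Socs2 (3.95 and -1.31), Bcl2 (2.11 and -0.02) and Cish (1.88 and -0.12). Amino acid and integrated stress response genes had medians of 0.39 (99.9th percentile) and -0.05, with the stress factor Atf3 82.6-fold and 3.48-fold higher and Vldlr at least 19.8-fold and 2.21-fold higher. TRP1low with K8 was the lowest of the 4 libraries in each of these lists, with a median against the mean of the other 3 of -0.91 for glycolysis, -0.80 for cholesterol synthesis, -0.93 for interleukin 2 and STAT5 targets and -0.70 for amino acid and stress genes.

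The 25 interferon-stimulated genes had a median of 0.57 (100th percentile) in TRP1high, with 18 above 0 and 7 below, and of -0.52 (0.01) in TRP1low, with 11 above and 14 below. Of these, 8 were higher and 4 lower with M9 in both TCRs. Isg15 was 13.4-fold and 2.23-fold higher with M9 and Rsad2 3.32 and 3.90 log2 higher, while Ifit3 was lower in both (-1.74 and -3.49). Irf7, the interferon-inducible transcription factor, was 2.48 higher in TRP1high and lower in TRP1low (-1.92). Cell cycle genes had small differences, with medians of -0.16 (percentile 1.64, 28 of 34 below 0) in TRP1high and -0.03 (8.47) in TRP1low, and 0 of 34 at least 2-fold apart in TRP1high and 1 in TRP1low. The 25 oxidative phosphorylation genes held medians of 0.09 and 0.10 and no member at 2-fold. Ribosome biogenesis genes had medians of -0.22 (percentile 0.20) and 0.06, and p53 and apoptosis genes 0.00 and -0.45 (percentile 0), with 4 of 19 lower in TRP1low, among them Sesn1 (-1.47) and Trp53inp1 (-1.49). For the peptide over both TCRs, camera called glycolysis (adjusted p = 3.4e-05) and cholesterol synthesis (0.0046) with the preset correlation, each with an adjusted p = 0.84 with an estimated correlation. The other 12 gene lists had adjusted p from 0.085 to 0.70.

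Transcripts of other cell types differed along with the peptide. B cell markers were lower with M9 in both TCRs: 22 of 24 at least 2-fold in TRP1high (median -3.62, percentile 0) and 13 of 24 in TRP1low (median -1.21, percentile 0), and the camera adjusted p was 4.0e-09 and then adjusted p = 0.84 with an estimated correlation. With values under the floor raised to it, the medians were -2.92 in TRP1high and -1.21 in TRP1low. Igkc, the kappa light chain constant gene, stood at log2 8.81 and 3.31 with K8 and M9 in TRP1high and at 9.05 and 6.24 in TRP1low, and Cd79a at 7.19, 1.99, 6.60 and 4.87. Pax5, the B lineage transcription factor, was at least 180-fold lower with M9 in TRP1high, and stood at 3.41 and 4.21 in TRP1low. Ighm did not follow, at 14.10, 13.97, 14.15 and 14.01. Cr2 and Spib had limma Benjamini-Hochberg adjusted p of 0.029 and 0.042 over the list alone. Mitochondrial reads made up 6.08% and 4.33% of TRP1high with K8 and M9, and 7.34% and 7.47% of TRP1low.

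CD8 T cell markers had a median of 0.43 (100th percentile) in TRP1high and 0.07 in TRP1low, with 0 of 14 at 2-fold in either. All 5 measured erythroid markers were higher in TRP1low with K8 than in TRP1low with M9 (median -5.73, Alas2 within the floor), with Hba-a2 at log2 7.93 there and at 0 in the other libraries and Hbb-bs at 7.75. In TRP1high that median was 0.45, and -0.01 with values under the floor raised to it. Myeloid or dendritic markers had a median of -0.30 (12.2) in TRP1high and -1.13 (0.12) in TRP1low, where 8 of 14 were lower with M9, among them Lyz2 at 5.53 and 1.63. Of the plasma cell markers, Jchain was 6.05-fold and 45.3-fold (7.91 to 1905) lower, and Xbp1 stood at 12.63, 12.43, 11.14 and 12.62 in TRP1high with K8 and M9 and TRP1low with K8 and M9. The CD4 gene Cd4 stood at 1.64, 0, 4.73 and 4.27 in the same order, and Trdc, the delta chain constant gene, at 9.40, 8.86, 10.20 and 9.64. The Y-linked gene Ddx3y was present in each library, at 10.69, 10.64, 10.98 and 10.76.

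Tested over both TCRs, 0 of 16102 genes passed for the peptide at an adjusted p of 0.05 (limma, Benjamini-Hochberg, lowest 0.58), and 1342 had an unadjusted p under 0.05. With the trend option of limma 5 genes passed, each at an adjusted p of 0.041: Crabp2 (6.33, SE 0.34), Cd200 (3.14, SE 0.21), Prf1 (3.12, SE 0.22) and Tnfrsf4 (2.54, SE 0.18) were higher and Cxcr3 was lower (-3.48, SE 0.25) with M9. The count was 0 with the robust option, without the covariate and under each other pseudocount, filter and scaling. Outside the cytotoxic, inhibitory, chemokine receptor and B cell lists, 0 members of any list passed when adjusted over the list alone.

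**Figure D2:**
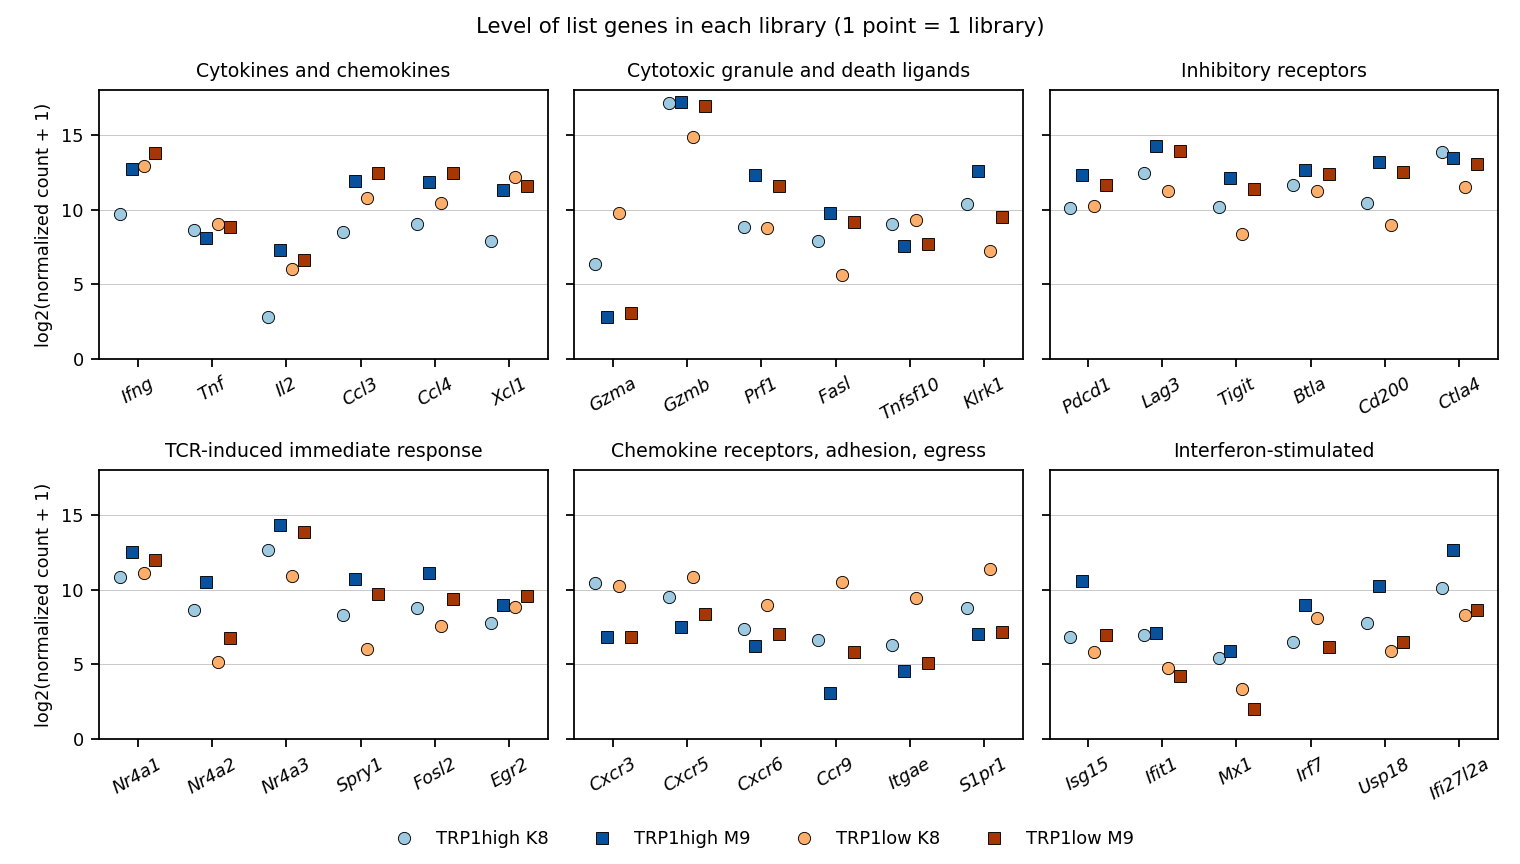
Level of 6 genes from each of 6 gene groups in each library, as log2(normalized count + 1), with 1 point per library (circles K8, squares M9, blues TRP1high, oranges TRP1low). Prf1, Pdcd1, Lag3, Tigit and Cd200 lie higher with M9 in both TCRs, Cxcr3, Ccr9 and S1pr1 lie lower, and Gzmb and Ctla4 are lowest in TRP1low with K8.

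The next comparison asks how cells with the TRP1high receptor differed from cells with the TRP1low receptor. With both peptides, TRP1high cells held more Klrk1, Nr4a2, Cd5 and Tnfrsf4, more of several interferon-stimulated genes and more Ly6c and Igfbp4 transcript, and less Ccr9 and Id2. Klrk1 (chromosome 6, 129610323 to 129623864) was 9.11-fold higher in TRP1high with K8 and 8.48-fold higher with M9. Nr4a2 (chromosome 2, 57106830 to 57124003) was 11.9-fold and 13.7-fold higher, and Nt5e, the ectonucleotidase CD73 (chromosome 9, 88327197 to 88372092), was 21.7-fold and 12.3-fold higher. Ccr9 was lower, by log2 differences of -3.89 and -2.71.

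At least 2-fold differences between the TCRs were seen for 3046 genes with K8 (1701 higher and 1345 lower in TRP1high, 18.9%) and for 2085 with M9 (1186 higher and 899 lower, 12.9%). Both peptides shared 521 of the higher and 368 of the lower genes, against 121.8 and 60.9 for independent lists, and 171 differed in opposite directions, against 172.4. Across 12708 genes the differences with the 2 peptides had a Pearson correlation of 0.55 and a Spearman correlation of 0.50. With at least 200 normalized counts in 1 library of each pair, 371 genes were shared, against 41.7, with a Pearson correlation of 0.74. Without pseudogenes and receptor segments, a choice also made after seeing the data, 725 genes were shared, against 145, at 0.47.

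Among the 10 highest genes, Myh7 and Myh6, neighbouring genes of cardiac myosin heavy chains (chromosome 14, 54970684 to 54994626 and 54941921 to 54966927), were at 0 in TRP1low and at least 11.7-fold and 11.9-fold higher in TRP1high with K8 and at least 45.7-fold and 43.1-fold higher with M9. Both lie near the Tra locus (52567198 to 53977678 on chromosome 14), and whether their difference stems from that position was not tested. Evc (at least 16.9-fold and 6.41-fold), Gldc, the glycine decarboxylase (at least 10.9-fold and 7.55-fold), and Gm43302 (at least 18.5-fold and 17.6-fold) were also at 0 in both TRP1low libraries, and Fam20a was at least 34.4-fold and 9.23-fold higher. Gbp2b, an interferon-inducible guanylate binding protein gene (chromosome 3, 142594847 to 142619179), was 61.7-fold lower in TRP1high with K8 and 957-fold lower with M9. The other 9 of the 10 lowest genes and 4 of the 10 highest were pseudogenes, which share reads with other genes, so that their values are uncertain. Rpl3-ps1 (chromosome X, 13202571 to 13203780), a pseudogene of the ribosomal protein gene Rpl3, stood at log2 6.83 and 0 in TRP1high and at 15.35 and 15.46 in TRP1low, and Gm3375 stood at 10.24 and 10.47 in TRP1high and at 0 in TRP1low.

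Of 25 interferon-stimulated genes, 12 were at least 2-fold higher and 4 lower in TRP1high with K8, 16 were higher and 0 lower with M9, and 10 were higher with both, with medians of 0.53 (99.8th percentile) and 1.78 (100th). Against the mean of the other 3 libraries, this list was lowest in TRP1low with M9 (-1.46), then in TRP1low with K8 (-0.71), and stood at 0.24 and 0.91 in TRP1high with K8 and M9. Ifi27l2a was 3.52-fold and 15.9-fold higher, Usp18 3.75-fold and 13.7-fold, Isg15 2.03-fold and 12.2-fold, and Mx1 4.44-fold (1.90 to 11.3) and 18.9-fold (5.94 to 91.0), the last against 3 reads. Camera gave this list an adjusted p of 7.3e-04, and the call was lost at an adjusted p = 0.83 with an estimated correlation. Of 22 naive and memory-associated genes, Igfbp4 (4.82 and 2.74), Dapl1 (2.001 and 3.78), Ly6c1 (3.37 and 2.26), Ly6c2 (2.19 and 1.89) and Il6ra (1.54 and 2.51) were at least 2-fold higher with both peptides and 0 were lower, with medians of 0.10 and 0.40 (99.99th percentile). Of 31 T cell receptor-induced genes, 4 were higher with both peptides (Nr4a2, Cd5 at 1.59 and 1.55, Fosl2 at 1.24 and 1.75, and Spry1 at 2.29 and 1.004), with medians of -0.05 and 0.47 (100th).

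With K8, the cytokine and metabolic lists stood further apart between the TCRs than with M9, a difference that was not tested. Per gene, this contrast equals that between the peptide differences of the TCRs, so it is no separate finding. Effector cytokines and chemokines had a median of -0.82 (percentile 0) with K8 and -0.26 (4.39) with M9, or -0.06 with M9 when values under the floor were raised to it. Ifng was 9.18-fold lower in TRP1high with K8 and 2.03-fold lower with M9, Xcl1 19.2-fold and 1.197-fold lower, and Csf2 32.9-fold (10.8 to 163) and 1.59-fold (0.771 to 3.38) lower. Medians with K8 and M9 were 0.82 and 0.23 for glycolysis, 0.87 and 0.17 for cholesterol synthesis, 0.73 and 0.21 for amino acid and stress genes, 1.18 and -0.06 for interleukin 2 and STAT5 targets, and 0.55 and 0.08 for activation receptors. Inhibitory receptors had medians of 0.64 and 0.36. With values under the floor raised to it these were 0.298 and 0.299, so that this list stood no further apart with K8. Il2ra was 7.01-fold and 1.28-fold higher in TRP1high, Gzmb 4.67-fold and 1.17-fold, and Mki67, a proliferation marker, 13.7-fold and 4.50-fold. Mki67 stood apart from its list: the 34 cell cycle genes had medians of 0.04 and -0.18. It was the only 1 of them at least 2-fold higher with both peptides. The TRP1low library with K8 was also the one with erythroid transcripts (median -5.71 with K8 and 0.28 with M9) and higher myeloid markers (-1.98 and 0.00). With values under the floor raised to it, the erythroid medians were -4.93 and -0.06. B cell markers were 0.57 higher (97.4) in TRP1high with K8 and lower with M9 (-1.06, percentile 0).

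Chemokine receptors had medians of -0.81 (percentile 0) with K8 and -0.33 (1.85) with M9, with 7 and 3 of 16 at least 2-fold lower in TRP1high and 1 higher each time, and camera did not call the list (adjusted p = 0.15). Medians of the remaining lists were -0.11 and 0.13 for cytotoxic genes, 0.36 and 0.16 for transcription factors, 0.04 and -0.18 for cell cycle genes, -0.11 and -0.11 for oxidative phosphorylation, 0.26 and -0.14 for ribosome biogenesis, and -0.33 and -0.10 for p53 and apoptosis genes. Runx3, a factor of the CD8 lineage, was 1.80 and 1.09 higher in TRP1high and Zeb2 1.34 and 3.12 higher, while Id2 (-1.12 and -1.37) and Ikzf2 (-1.23 and -1.03) were lower. CD8 T cell markers had medians of 0.00 and 0.30. Tcrg-C1 and Tcrg-C2, gamma chain constant genes, were higher in TRP1high, Tcrg-C1 at log2 9.83 and 6.73 with K8 and M9 against 3.40 and 1.63 in TRP1low, and Tcrg-C2 by 34.0-fold and by 20.75-fold (6.80 to 103).

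Over both peptides, 0 of 16102 genes passed for the TCR in limma with Benjamini-Hochberg adjustment (lowest adjusted p 0.32), and 2044 had an unadjusted p under 0.05. The trend option called 260 (165 higher and 95 lower in TRP1high) and the model without the covariate 44 (11 and 33), while the robust option called 0. With trend, the adjusted p was 0.011 for Nr4a2 (3.65, SE 0.30), 0.0029 for Klrk1 (3.13, SE 0.18), 0.014 for Cd5 (1.57, SE 0.14), 0.016 for the interferon-stimulated gene Zbp1 (1.75, SE 0.16) and 0.045 for Ccr9 (-3.30, SE 0.48). Adjusted over the list alone, with trend off, Klrk1 (0.030), Nt5e, Cd200r1 and Tox2 (each 0.045, Tox2 at few reads), Nr4a2 (0.039), Trbc1 (0.044), Cd4 (0.037), Tcrg-C1 and Tcrg-C2 (each 0.012) passed. Camera also called cholesterol synthesis (adjusted p = 0.0023), glycolysis (0.0047) and amino acid and stress genes (0.022), each with an adjusted p = 0.83 with an estimated correlation.

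**Figure D3:**
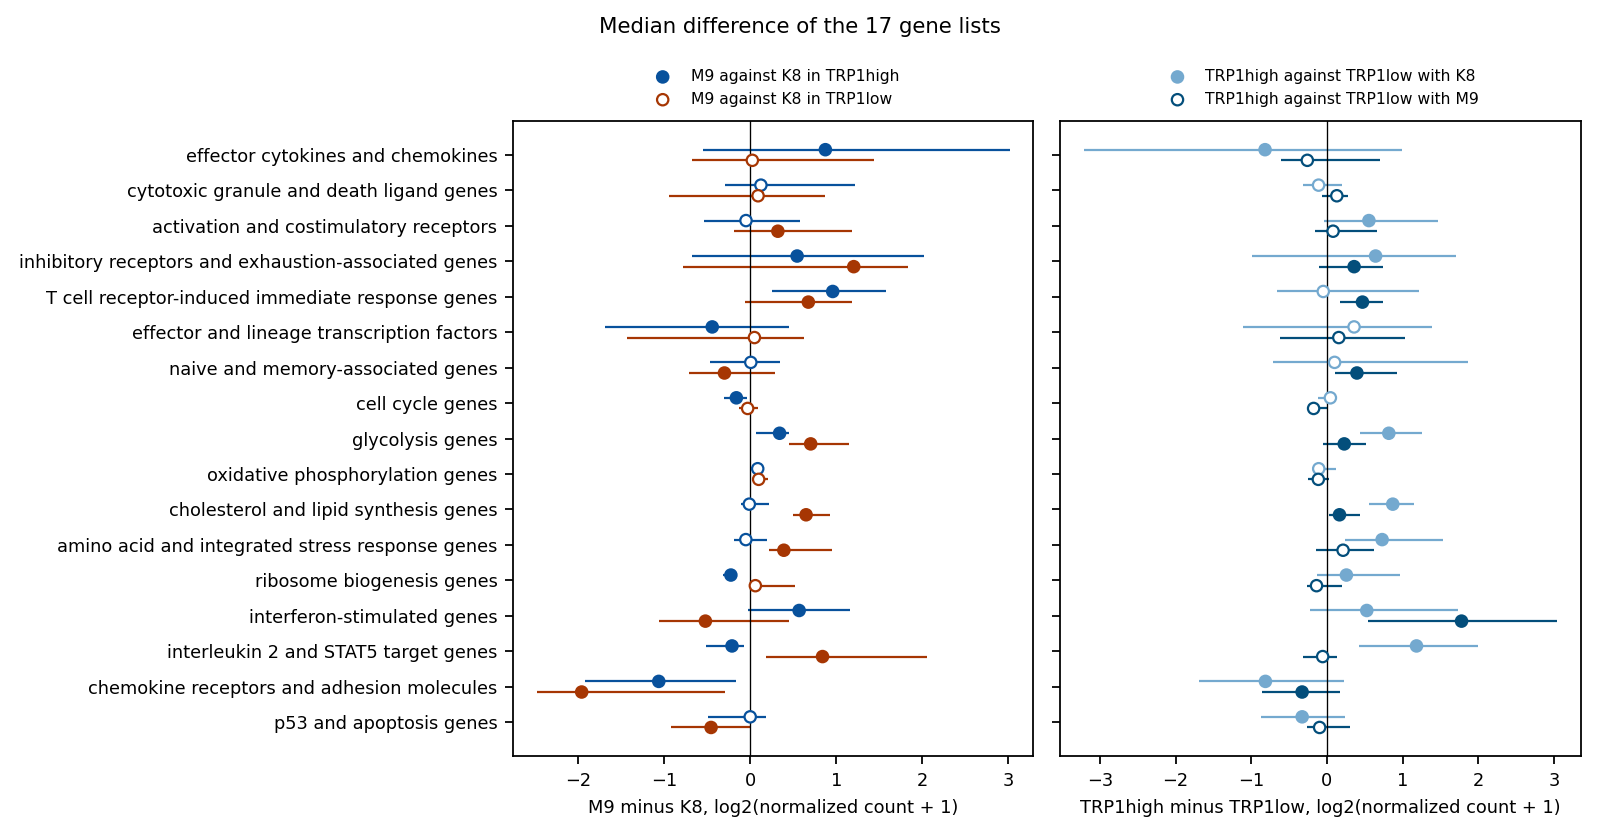
Median log2 difference of the measured members of each of the 17 gene lists, for M9 minus K8 in each TCR (left panel) and TRP1high minus TRP1low with each peptide (right panel), with bars from the 25th to the 75th percentile of the members. Filled points lie outside the central 95% of 10000 random lists, such as T cell receptor-induced genes at 0.96 and 0.68 and chemokine receptors at -1.06 and -1.96 on the left.

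The last comparison asks where the peptide difference itself differed between the TCRs. Per gene, this equals the contrast between the TCR differences with M9 and with K8, so its list values restate contrasts given above. The difference of differences was at least 2-fold for 3019 of 13871 genes, 1460 with a more positive M9 minus K8 difference in TRP1high and 1559 with a more negative one. The most positive were Gm3436, Gm29462, Ccl1, Itga2b and Stard13, and the most negative Gm9923, Pax5, Gm4540, Gm21182 and Gm4202, among which Ccl1, Itga2b, Stard13 and Pax5 are genes other than pseudogenes. Ccl1, a chemokine gene (chromosome 11, 82176657 to 82305690), was at 0 and 3 reads in TRP1high with K8 and M9, and at least 57.7-fold lower with M9 in TRP1low. Itga2b and Stard13 were higher with M9 in TRP1high (2.79 and 3.71) and lower in TRP1low (-6.55 and -5.27). Among the lists, the median difference of differences was 1.69 for interferon-stimulated genes and 0.86 for cytokines (both at the 100th percentile), and -1.08 for interleukin 2 and STAT5 targets, -0.59 for cholesterol synthesis and -0.49 for glycolysis (each at percentile 0). With 4 libraries and 4 groups no spread was left to test these differences.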

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

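Results stand here because the M9 minus K8 difference was at least 2-fold in both TCRs but in opposite directions, or because a list's median lay outside the central 95% of random lists in opposite directions. With 1 library per group, none of these differences between TCRs was tested. The tests of depth, of dilution, of B cell amounts and of reads assigned to a gene's own pseudogene were chosen after the results were seen. Tests first framed on the genes that showed the B cell and pseudogene patterns were replaced, since they had only 1 way to come out. The replacements used 11 of 24 B cell markers, picked by their level in TRP1high with K8. For pseudogenes they used the 23 of 136 with a named parent, all already 2-fold apart between the TCRs. Neither set is thus free of selection. The test of B cell genes among the lower genes and that of linkage to the receptor loci were chosen before their results were seen. The B cell test met the bound written beforehand against B cells as the main source. That verdict was withdrawn after the result was seen, since the lists were too short for the test to decide. The bound applied for the opposite outcome also differed from the written one.

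Interferon-stimulated genes had a median difference of 0.57 in TRP1high and -0.52 in TRP1low, and the median over their genes of the difference between the TCRs was 1.69. For interleukin 2 and STAT5 targets the medians were -0.21 and 0.84, and the median of the difference was -1.08. Differences of differences (TRP1high minus TRP1low) of single list members were 9.503 for Ccl1, 4.98 for Ccr8, 4.01 for Csf2, -4.44 for Entpd1, 2.22 for Ifih1, -4.12 for Il24, 4.39 for Irf7, -5.26 for Socs2 and -3.03 for Foxp3. Among markers and other named genes they were -6.68 for Ebf1, 7.33 for Hba-a1, 8.32 for Impg2, 9.34 for Itga2b and 8.98 for Stard13. Ccl1 in TRP1high, and Il24 and Impg2 in TRP1low, were within the floor with both peptides. Foxp3 in TRP1low was under the floor with K8 and near it with M9, so that its direction there is uncertain. Gm10273 (6.66), Gm21182 (-8.70), Gm29462 (9.70), Gm3436 (9.84), Gm4540 (-9.64) and Gm9923 (-12.01) are unnamed gene models or pseudogenes with uncertain values.

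B cell markers were lower with M9 in both TCRs. B cells were the presenting cells, so that B cells left after sorting in different amounts are a candidate explanation. A single source should move its transcripts by 1 ratio if no other cell supplies them. The 11 markers from 100 to 1000 in TRP1high with K8 had an interquartile range of 2.92 around a median of -3.12, and Ighm did not follow. Reads of these markers that did not come from B cells would also widen that range. Amount, altered B cell expression and such reads cannot be told apart by this test. How many of the other lower genes came from B cells also stays open: 7.94% of the 252 genes lower with M9 in both TCRs were B or plasma cell markers or immunoglobulin segments, but 35 such genes were compared, so that the share had 13.9% as its limit and decides nothing.

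TRP1low with K8 stood apart from the other 3 libraries, with 1447 genes of at least 100 normalized counts 2-fold from their mean, against 698, 948 and 576 for the others. For the interleukin 2 and STAT5 list lower depth is an unlikely source, since its 12 members with a mean of at least 1000 normalized counts had a median of -1.17. These are 12 of the 14 members of a list already seen to be low, so the limit of 1000 tested little beyond the list itself. Whether depth added to the 1447 genes was not tested. Markers of other cells were higher in this library than in the mean of the other 3, with medians of 5.18 (erythroid), 1.79 (myeloid or dendritic) and 0.88 (B cell). B cell markers did not set it apart, since their median was 2.22 in TRP1high with K8. Dilution by other cells large enough to lower the interleukin 2 and STAT5 list is argued against, as CD8 markers without receptor genes had a median of -0.196. A culture or sorting difference of this 1 library and a lower response of TRP1low cells to K8 both stay open and were not tested, and a replicate would be needed to part them.

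Pseudogenes made up 136 of 861 genes (15.8%) 2-fold apart between the TCRs with both peptides, against 8.71% of tested genes. If reads of a gene went to its own pseudogene, the 2 should differ in opposite directions: 60.9% (14 of 23, exact interval 38.5 to 80.3) did, which leaves this open. In the 6 pairs whose pseudogene reached 1000 normalized counts, a limit chosen after the values were seen, the TCR difference of the parent and of the summed pair was 0.87 and 0.13 for Rpl3, 1.13 and -0.03 for Rpl34 with Rpl34-ps1, 0.37 and -0.04 for Rps2, 0.54 and -0.88 for Rps13, -0.19 and -0.40 for Pcna and -0.03 and -0.09 for Rps15a with Rps15a-ps8. The sum lay nearer 0 than the parent in 3 of these. Genes within 20 Mb of the receptor loci were 2-fold apart 1.41 times as often as others (8.74% against 6.18%), with 10.05% (22 of 219) at Tra and 6.80% (10 of 147) at Trb, so that a chromosome stretch from another strain also cannot be told apart from none, and strain variants in the reads were not analysed here.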

How the results depend on the processing

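The trend option of limma and removal of the covariate were alternatives planned with the others, and the minimum of 200 normalized counts and the removal of pseudogenes were chosen after the data were seen. Direction was checked under the other pseudocounts, filters and scalings, for the genes named by the rule and for list medians over both pairs. Among these, no difference of at least 2-fold and no list median outside the central 95% of random lists changed direction. For single genes this outcome was nearly fixed in advance. A filter leaves a gene's value unchanged, and a pseudocount keeps the sign of a difference between 2 libraries. Rescaling by the median ratio shifted all genes by far less than 2-fold. The direction check is thus weak support for single genes. Other genes, and list medians of the single comparisons and of the difference of differences, were not checked in this way. At 1.5-fold the counts were 3159 (M9 against K8 in TRP1high), 4347 (TRP1low), 5351 (TCRs with K8), 4168 (TCRs with M9) and 5005 (difference of differences). With at least 50 in 1 library they were 768, 1338, 1915, 1166 and 1593, and with at least 200 they were 424, 806, 1287, 710 and 940, with 147 and 371 genes shared for the peptide and the TCR. These counts move because each alternative admits more or fewer genes by construction. limma with trend called 5 genes for the peptide and 260 for the TCR, and without the covariate 44 for the TCR; the cause was not tested. The other 76 values of counts, calls and agreement stayed within 1.5 times or at 0. Of the values of single genes and list medians, 1523 stayed within their limits, among them all single-gene values under the filters, which could not change. The other 57 moved. Of those, 34 values of single genes moved with a pseudocount of 5 and 16 with 0.1, all of genes at few or 0 reads in at least 1 library, 3 with median-ratio scaling and 2 with the removal of receptor, immunoglobulin, mitochondrial and B cell genes, and the erythroid median moved to -1.76 for the peptide with a pseudocount of 5 and to -3.21 for the TCR with 0.1. For the peptide over both TCRs, the call of a list outside the central 95% of random lists ended for effector and lineage transcription factors (-0.41 to -0.13, percentile 10.2) and myeloid markers (percentile 2.74) with a pseudocount of 0.1, and for CD8 markers (0.31 to 0.11, percentile 90.9) with that removal. It was gained by cytotoxic genes (0.09 to 0.32, percentile 99.94) with a mean of at least 5. No list's call for the TCR changed. No library could be left out, since each is the whole of its group. TRP1low with K8 was the least deep library, with 1205 genes at 0, so that low genes there are known only to its floor of log2 2.35.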

Other observations

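Values in this part come from no test. B cell marker levels differed among genes of the same cell type: H2-Ab1 stood at log2 8.76, 9.40, 7.74 and 7.74 in TRP1high with K8 and M9 and TRP1low with K8 and M9, while H2-Aa stood at 8.61, 3.62, 8.06 and 6.53 and Cd74, the invariant chain, at 10.40, 9.34, 10.29 and 8.55. Foxp3 stood at 4.55, 2.60, 1.26 and 2.35, and Izumo1r, which encodes folate receptor 4, at 10.45, 10.68, 8.17 and 10.40. Zbtb7b, a factor of the CD4 lineage, stood at 5.77, 6.73, 1.77 and 6.61.

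The 10 most abundant genes held 7.98%, 7.59%, 8.72% and 9.06% of the normalized counts in the same order. The Y-linked genes Kdm5d (9.52, 9.13, 10.18 and 9.82), Eif2s3y (11.62, 11.71, 11.77 and 11.70) and Uty (9.45, 9.19, 10.21 and 9.58) were present in all 4 libraries.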
